A study of Mus musculus with 4 samples.

How the data were processed

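Haematopoietic stem cells (HSCs), the bone marrow cells that give rise to all blood lineages, were sorted from male C57BL/6 mice aged 20 months that carried a tamoxifen-inducible Cre recombinase at Pdzk1ip1 and a tdTomato reporter at the Rosa26 locus. Per the labels' protocols, cells from 2 mice were pooled 7 days after 1 mg of tamoxifen, about 33000 cells negative for lineage markers and CD48 and positive for Sca-1, c-Kit and CD150 were collected without selection on tdTomato, and between 5000 and 7000 nuclei were loaded for a target of 4000 on a droplet platform that reads chromatin accessibility and RNA from the same nucleus. Whether these numbers hold for each library is not said. The labels list 4 accessibility libraries of 1 group, named sample 5 to sample 8, and nothing says that they came from separate animals.

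The deposited files were a list of cell barcodes and a list of features, each made by the authors for the series as a whole. Per the submitters' processing notes, Cell Ranger ARC 2.0.0, Seurat 4.3.0 and Signac 1.9.0 were used on the mouse build mm10 (GRCm38). The role of each tool, the settings of the peak caller and the settings of the cell caller are not given in the sources used here. In the deposited feature list each row holds a gene identifier with its symbol, or a peak position, and a feature type. It holds 32285 genes and 143586 peaks, and carries no read count, height, score or p-value for a peak and no column for a library. The deposited barcode list holds 20000 barcodes of 16 bases with no library name. A matrix of values per cell was not analysed here, so the depth of each library is unknown, no value could be given per library or per cell, and no test between libraries was possible. Peaks were taken as 1 set called over the pooled libraries, an assumption that the files do not settle. Intervals given below cover counting error only, and genes within this 1 peak set are not replicates, so no p-value across genes was computed.

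Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the same build as the files, which gives the start and end of each gene but neither its strand nor its exons. Of the listed genes, 26335 were matched by symbol and 361 by a synonym held by 1 gene. Another 5589 were not matched, and 72 were left out because their RefSeq position was already taken, which left 26624 genes. Named genes, 20765 in number, leave out symbols of predicted genes, Riken and clone names, pseudogenes and mitochondrial genes. A first run used a wider filter on clone names than the design, and counted a gene's own ends in the matching. Both were changed to the design after list placements had been seen, and both earlier forms were kept as alternatives. Peak positions are printed as the feature names give them. The design fixed before the data were examined used transcription start sites. The feature list holds no start sites and the table no strand. A gene was therefore scored for a peak overlapping by at least 1 bp the region within 1 kb of either of its ends. These ends bound the gene as annotated, and a start site inside a gene was not scored. A gene without a peak at an end may thus still have a peak at a start site in use. A second measure was the number of peaks within 50 kb of a gene end, taken as the mean over both ends. Genes that lie close together share part of these windows, so this number describes a region and not a gene alone. Such neighbours are Slc17a7 and Rpl13a, Nupr1 and Sult1a1, and Gp6 and Ncr1, all on chromosome 7. Peaks on unplaced sequences were left out of both measures.

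The 22 gene lists were fixed before the data were examined. Each list was placed among 10000 random lists of the same size drawn with replacement from named genes and matched on the quintile of the number of other gene ends within 50 kb. A list was called above or below where its percentile was at least 97.5 or at most 2.5. Random members were drawn independently of each other. Some lists hold neighbours that share windows, such as Prtn3 and Elane, Ppbp and Pf4, or Tal1 and Pdzk1ip1. For such lists the random spread may be too narrow. With 44 placements, chance alone would put 2.2 outside these limits. Differences between pairs of lists were placed among 10000 random reassignments of their members, for pairs chosen after the data were seen, and again under each setting of the peaks and windows. Erythroid gene Ahsp had no position and was left out. The named-gene rule took Pdzk1ip1, the sort and lineage genes, and Flt3, Il7r, Rag1, Ebf1 and Pax5. From each list it took the 2 members with the most peaks within 50 kb among those with a peak at an end and the 2 with the fewest among those without. It added the 10 named genes with the most peaks within 50 kb and the 5 widest peaks. A gene that this rule takes is not reported here. Shares have exact Clopper-Pearson 95% intervals. Enhancers were scored at 12 positions given by their usual distance from the promoter, within 1.5 kb. The distance was counted from the outer gene end, so a position is misplaced where the promoter lies inside the annotated gene. Distances and strands were written from general knowledge before the data were examined, are not in the files and were not checked against a source.

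Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Interval counting was tested on simulated data and gave 0 differences from a direct count over 4000 intervals. Of 200 simulated unchanged lists of 20 genes, drawn from the 20765 named genes, 6.0% were called. Of 200 lists with a true share of 98%, 82.5% were called above. These simulated lists gave each gene a peak independently and tested the share only. They do not cover lists of neighbouring genes or the number of peaks within 50 kb. Alternatives varied the window, the overlap, the peak width, the gene background and the matching. A search for transcription factor motifs, matching on GC content and a leave-out of libraries were planned and were not run: no genome sequence was used here, and the files do not separate the libraries.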

Results

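Accessible chromatin was profiled in HSCs of 20-month-old male mice, sorted by surface markers without regard to the tdTomato reporter. The design holds 1 group of 4 libraries and no young group, so the data describe which regions were called accessible in old HSCs as a whole. Cells of 2 mice were pooled, and the labels do not say how each library relates to that pool. The barcode list held 20000 barcodes, and the feature list named 143586 accessible regions (peaks). The number of reads behind each peak is unknown, and a peak that is missing may have been closed, or too rare or too shallow to be called. The comparisons below ask how the peaks were distributed along the genome, and how genes of the HSC programme and of the lymphoid, myeloid, erythroid and platelet lineages compared with other genes.

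Most peaks of old HSCs lay away from gene ends. Of 143533 peaks on chromosomes 1 to 19, X and Y, 22813 (15.9%, 95% interval 15.7 to 16.1) were within 1 kb of an annotated gene end. When the same peaks were shifted along their chromosomes, 5.28% were (100 shifts, range 5.02 to 5.76%), a 3.01-fold lower share. A further 48.8% of peaks lay inside gene bodies and 35.4% between genes, both more than 1 kb from any gene end. The median distance of these 120720 peaks to the nearest gene end was 17.0 kb, and 18.3% of all peaks were over 50 kb away. Peaks had a median width of 879 bp (5th to 95th percentile 675 to 925 bp) and together covered 122 Mb without overlapping.

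A peak was found within 1 kb of an end in 15571 of 20765 named genes (74.99%, 95% interval 74.4 to 75.6). Among 13044 protein-coding genes longer than 10 kb, 63.0% had a peak at 1 end, 21.7% at both ends and 15.3% at neither. If the ends are independent, these shares correspond to 78.9% at the more frequently marked end and 27.4% at the other. For comparison, the midpoints of 9460 genes longer than 20 kb had a peak in 21.3%. Strand was not used, so the end that carries a peak is not named as a promoter here. By annotated class, 74.2% of 20941 protein-coding genes had a peak at an end, against 56.6% of 4726 long non-coding RNA genes and 15.6% of 205 pseudogenes.

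The genes used to label and sort these cells had peaks at an end, as did 74.99% of all named genes. Pdzk1ip1, whose locus drives the inducible Cre, lies on chromosome 4 at 115088708 to 115093894 (GRCm38), had a peak at 115088437 to 115089340 over its start coordinate, and had 23 peaks within 50 kb, at percentile 98.04 of named genes. Kit, the stem cell factor receptor, had peaks at both ends of its gene on chromosome 5 (75574987 to 75656722) and 11.5 peaks within 50 kb. Ly6a, which encodes Sca-1, had a peak at 74995272 to 74996107 on chromosome 15 and 16 within 50 kb. Slamf1, which encodes CD150, had a peak at 171766790 to 171767603 on chromosome 1 and 13.5 within 50 kb. Cd48, whose product was absent from the sorted cells by gate, also had peaks at its start coordinate, at 171680691 to 171681406 and 171681591 to 171682464, and 17 within 50 kb. Among genes of the lineage depletion, Ptprc (the CD45 locus, of which B220 is an isoform), Itgam (CD11b) and Klrb1c (NK1.1) had a peak at an end. Ly6g, a granulocyte surface gene of the Gr-1 antigen, had none, with 13 peaks within 50 kb. For peaks within 50 kb, Kit, Slamf1 and Ly6a lay at percentiles 57.9, 69.7 and 81.8 of named genes, and Cd48 at 85.7. The lineage genes Ptprc, Ly6g, Itgam and Klrb1c lay at 42.9, 66.8, 79.7 and 98.9. This number did not separate genes of the sorted cells from those of excluded cells. Genes such as Ly6a, Ly6g and Klrb1c have close copies nearby, and how reads shared between copies were treated is not given in the sources used here.

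**Figure D1:**
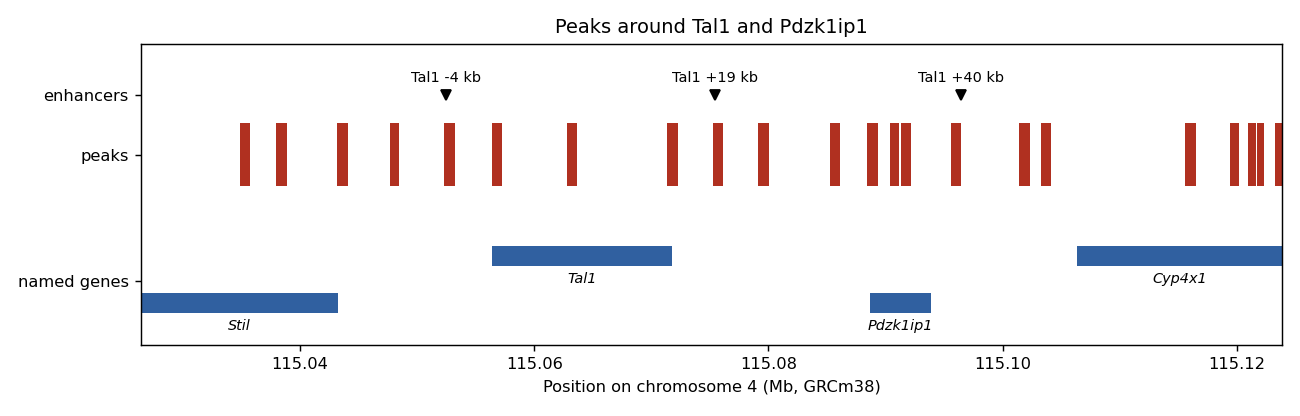
Map of chromosome 4 from 115026426 to 115123894 (GRCm38) drawn to scale, with position in Mb on the horizontal axis. Red boxes are the 22 peaks, blue boxes the 4 named genes (a gene reaching past an edge is drawn up to it), and triangles mark the 3 positions at the usual distances of Tal1 enhancers, each of which has a peak within 1.5 kb.

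All 30 genes of the HSC identity list had a peak at an end (100%, 95% interval 88.4 to 100), which placed the list at percentile 99.99 of 10000 random lists. The middle 95% of random lists ran from 60 to 90%. The list had a median of 14 peaks within 50 kb (interquartile range 11.1 to 19), against 6.75 to 12.25 in random lists (percentile 99.985), and 24 of 30 members exceeded the median of all named genes, 10 peaks. Hoxb5, a homeobox gene used as an HSC marker, had 31.5 peaks within 50 kb, and Lyl1, a basic helix-loop-helix factor of blood progenitors, had 26. The call on the share of genes with a peak at an end was lost when the peak had to cover the gene end itself (percentile 88.2) and went to percentile 8.28 with peaks of at least 900 bp, a limit set after the data were seen.

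Genes linked to the ageing of HSCs had a peak at an end in 23 of 25 cases (92%, 95% interval 74.0 to 99.0; percentile 97.3, within random lists) and a median of 12 peaks within 50 kb (percentile 97.9, above). Gpr183, a chemoattractant receptor, and Nupr1, a stress-induced chromatin protein, had 25 peaks each within 50 kb. Osmr, the oncostatin M receptor, had no peak at an end and 4.5 within 50 kb, and Sult1a1, a sulfotransferase, had none at an end and 20.5 within 50 kb. Neither call is firm. A second draw of random lists put the share at percentile 97.7, above, and the call on the median ended at 100 kb (89.1), with peaks near gene ends left out (92.4), without matching (86.3) and with other settings chosen after the data were seen (88.5 to 97.3). The difference from the HSC identity list was within reassignment for both measures (-8 percentage points, with the middle 95% of reassignments from -8 to 6.67, and -2 peaks, from -3.5 to 3.5). At 100 kb the ageing median was below by -6.25 peaks (percentile 1.29), and with peaks of at least 900 bp the ageing share was above by 35.3 points (percentile 99.7). No young HSCs were measured in these files, so no change with age is given.

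Lineage genes of platelets, red cells and myeloid cells were widely marked. Of 20 megakaryocyte and platelet genes, 18 had a peak at an end (90%, 95% interval 68.3 to 98.8; percentile 94.7), and the median was 17 peaks within 50 kb (percentile 99.995). Gp1ba, a subunit of the platelet receptor for von Willebrand factor, had 26 and Zfpm1, the GATA cofactor FOG1, had 23.5, whereas the collagen receptor Gp6 (2.5) and the platelet chemokine Ppbp (12) had no peak at an end. In the myeloid list, 22 of 23 genes had a peak at an end (95.7%, 95% interval 78.1 to 99.9; percentile 99.4), with a median of 15.5 peaks within 50 kb (percentile 99.955) and the neighbouring granule protease genes Prtn3 (25.5) and Elane (25) highest. Erythroid genes had a peak at an end in 18 of 19 cases (94.7%, 95% interval 74.0 to 99.9; percentile 98.4) and a median of 13.5 peaks within 50 kb, within the range of random lists (percentile 91.7). Ermap and Klf1, an erythroid membrane protein and an erythroid transcription factor, had 19 each. The erythroid gene without a peak at an end was Gata1, the X-linked master regulator of red cells and megakaryocytes, with 12 peaks within 50 kb. Start sites inside its annotated span of 17404 bp were not scored, so a promoter without a peak is not shown. Protein-coding genes on X also had a peak at an end less often (62.9%) than those on autosomes (mean 83.1%). Against protein-coding genes without chemosensory receptors, the myeloid and erythroid shares lay at percentiles 95.4 and 90.5, no longer above. Both calls also ended within 500 bp (95.3 and 97.0), at the gene end itself (94.2 and 85.4) and with peaks of at least 900 bp (73.6 and 41.8). The erythroid call ended within 2 kb (96.3) and the myeloid call with an overlap of 100 bp (97.25). With peaks of at least 900 bp the platelet median lay at percentile 51.7. The platelet and myeloid lists hold neighbouring genes with shared windows, so their random ranges may be too narrow.

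Genes of lymphoid progenitors had a peak at an end in 18 of 22 cases (81.8%, 95% interval 59.7 to 94.8), within the range of random lists (percentile 71.6), and a median of 12.75 peaks within 50 kb, above them (percentile 98.4). Flt3, a cytokine receptor of lymphoid-primed progenitors, had peaks at both ends and 18.5 within 50 kb. Il7r, the interleukin 7 receptor, had a peak at 9529506 to 9530358 on chromosome 15 and 8.5 within 50 kb. Ebf1, a B lineage transcription factor, had peaks at both ends of its long gene and 5 within 50 kb. Ccr7, a homing receptor, and Ikzf1, the lymphoid regulator Ikaros, had 23.5 and 20 peaks. The 4 genes without a peak at an end were Rag1, a component of the V(D)J recombinase, and Mef2c, each with 10 peaks within 50 kb, and Ccr9 and Dntt (terminal transferase), with 12 and 15, which were named after their values were seen. The share of genes with a peak at an end was lower than in the HSC identity list by -18.2 percentage points, at percentile 1.36 of reassignments and on the edge of their middle 95% (-18.2 to 13.3). This call ended within 500 bp, within 2 kb and at the gene end itself (percentiles 12.3, 8.64 and 15.0), and the direction turned with peaks of at least 900 bp (15.2 points, within reassignment). The difference from the myeloid list was -13.8 points (percentile 9.17) and -2.75 peaks (percentile 3.08, middle 95% from -3 to 3), and that from the platelet list -8.18 points (percentile 24.2) and -4.25 peaks (percentile 4.15, from -4.75 to 4.75), each within reassignment. The call on peaks within 50 kb was lost at 100 kb (percentile 95.8), with peaks near gene ends left out (95.9) and without matching (93.9).

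The 2 lists named for mature lymphocytes did not stand apart from random lists. The mature B cell list also holds Vpreb1, Vpreb3 and Igll1, genes used chiefly in B cell precursors, so it is not limited to mature cells. Of its 16 genes, 12 had a peak at an end (75%, 95% interval 47.6 to 92.7, percentile 55.9). Vpreb1 and Vpreb3 were among the 4 without. Of 22 mature T and NK cell genes, 16 had a peak at an end (72.7%, 95% interval 49.8 to 89.3, percentile 38.9). Their medians within 50 kb were 13.25 (percentile 80.2) and 13 (percentile 96.2). At 100 kb the T and NK median was above random lists (percentile 98.8). Both shares were below that of the HSC identity list, by -25 points (percentile 0.535 of reassignments) and -27.3 points (percentile 0.185). Both calls ended at the gene end itself (percentiles 6.61 and 4.73), the former also within 2 kb (17.4) and the latter within 500 bp (6.55), and both directions turned with peaks of at least 900 bp (8.33 and 10.6 points, within reassignment). Pax5, the B cell commitment factor, had a peak at 44710497 to 44711374 on chromosome 4 and 5.5 within 50 kb. The B cell receptor component Cd79b (22) and the coreceptor Cd72 (21.5) had a peak at an end, and Ms4a1 (CD20, 6) and Vpreb3 (11) had none. Among T and NK genes, Klrb1c (24.5) and the coreceptor Cd4 (20.5) had a peak at an end, whereas the NK receptor gene Ncr1 (1.5) and the T cell signalling gene Themis (2) had none.

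**Figure D2:**
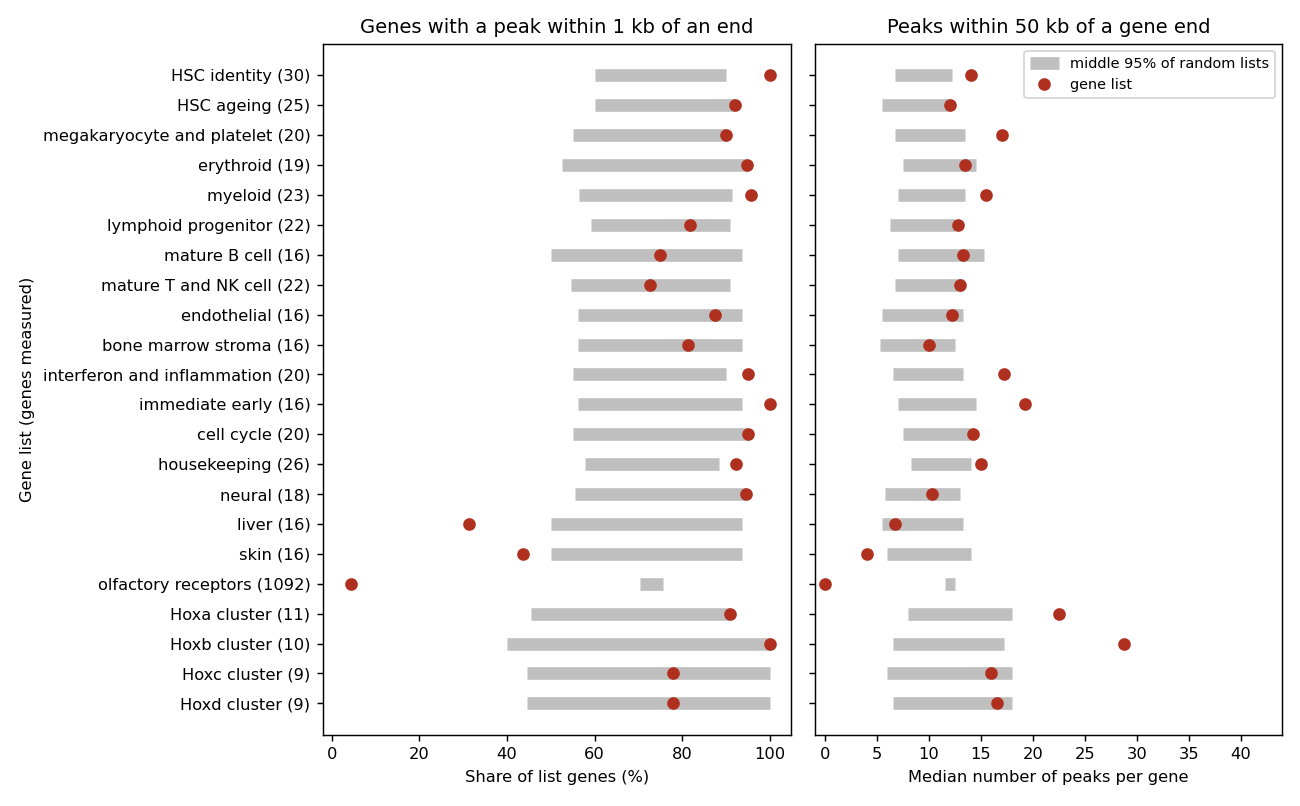
Placement of the 22 fixed gene lists, with the number of genes measured in brackets. Red points are the share of list genes with a peak within 1 kb of an end (left, %) and the median number of peaks within 50 kb of a gene end (right), and grey bars are the middle 95% of 10000 random lists. HSC identity lies at 100% and 14 peaks, right of both bars, and liver, skin and olfactory receptor genes lie at 31.2%, 43.8% and 4.304%, left of the bars of the left panel.

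Genes of tissues outside blood were marked less often in part of the lists. Liver genes had a peak at an end in 5 of 16 cases (31.2%, 95% interval 11.0 to 58.7; percentile 0.01) and a median of 6.75 peaks within 50 kb, within random lists (percentile 8.22). The liver median was below at 10 kb (1.35), matched on length (2.28) and against protein-coding genes (2.36). With peaks of at least 900 bp the liver share was within random lists (22.5). The lipoprotein gene Apoa1 (11) and the fetuin gene Ahsg (7.5) had a peak at an end, with none within 50 kb of Cyp3a11, a drug-metabolising cytochrome, or Serpina1a, a protease inhibitor. Liver genes were below HSC identity genes by -68.8 points (percentile 0 of reassignments), a difference that turned to 2.08 points, within reassignment, with peaks of at least 900 bp. Skin genes had a peak at an end in 7 of 16 cases (43.8%, 95% interval 19.8 to 70.1; percentile 0.61) and a median of 4 within 50 kb (percentile 0.29). The skin median was no longer below at 10 kb (7.31), nor the skin share with peaks of at least 900 bp (21.0). Krtdap (21) and the keratin gene Krt1 (10) had a peak at an end, and there were none within 50 kb of the desmoglein gene Dsg1a and 1 near the filaggrin gene Flg. Of 1092 olfactory receptor genes, 47 had a peak at an end (4.304%, 95% interval 3.18 to 5.68; percentile 0), and their median was 0 peaks within 50 kb. Olfr750 (18) and Olfr222 (17) had the most among those with a peak at an end, and Olfr1 and Olfr1014 had 0. Neural genes, in contrast, had a peak at an end in 17 of 18 cases (94.4%, 95% interval 72.7 to 99.9; percentile 97.7, next to the limit), Slc17a7, a vesicular glutamate transporter, with 21.5 peaks within 50 kb and Grin1, a glutamate receptor subunit, with 16.5, while the glial gene Gfap had none at an end and 9 within 50 kb. Slc17a7 lies near the housekeeping gene Rpl13a and shares much of its window, so its number is not particular to a neural gene. The neural median within 50 kb, 10.25, was within random lists (percentile 64.8), and the share was no longer above against protein-coding genes (92.5). Its call also ended within 500 bp (71.5), within 2 kb (95.1), at the gene end itself (65.0) and with peaks of at least 900 bp (70.5). Bone marrow stroma genes (13 of 16; percentile 66.2) and endothelial genes (14 of 16; percentile 85.5) were within random lists for this share, and their medians within 50 kb were 10 (percentile 68.2) and 12.25 (percentile 92.5). Sp7 (21) and Pdgfrb (17) led the stroma list, in which Dcn (0.5) and Ibsp (6.5) had no peak at an end. Plvap (22) and Nos3 (21.5) led the endothelial list, in which Stab2 (7.5) and Cdh5 (10) had none.

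Immediate early genes and interferon and inflammation genes were among the most densely marked lists, with cell cycle and housekeeping genes less so. All 16 immediate early genes had a peak at an end (95% interval 79.4 to 100; percentile 99.5), with a median of 19.25 peaks within 50 kb (percentile 100), led by the AP-1 genes Fosb (27.5) and Fos (27). Interferon and inflammation genes had a peak at an end in 19 of 20 cases (percentile 98.9) and a median of 17.25 (percentile 100). In this list the class II gene H2-Ab1 had 26.5 peaks within 50 kb and Socs3, a feedback inhibitor of cytokine signalling, 26, and Il1r1, the interleukin 1 receptor gene, had none at an end and 14 within 50 kb. Cell cycle genes (19 of 20; percentile 98.5) had a median of 14.25 peaks (percentile 98.005) and housekeeping genes (24 of 26; percentile 98.6) a median of 15 (percentile 99.4). Aurkb (25.5) and Ccnd1 (19.5) led the former among members with a peak at an end. In the same list the cyclin-dependent kinase inhibitor Cdkn1a had 20 peaks within 50 kb but none at an end, and start sites inside the gene were not scored. Rpl13a and Tubb5, with 24.5 each, led the latter, in which Reep5 (11.5) and Ywhaz (14) had none at an end. Against protein-coding genes without chemosensory receptors these 4 shares were at percentiles 96.9, 94.8, 91.4 and 87.8, in the order immediate early, interferon, cell cycle and housekeeping, and none was then above. The medians of cell cycle (94.0) and housekeeping genes (97.4) were not above there either, nor was cell cycle matched on length (96.7) or housekeeping at 10 kb (87.4) or with peaks of at least 900 bp (82.8).

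The Hox clusters, arrays of homeobox genes that pattern the body axis and in part mark HSCs, differed in peak number. Hoxb genes had a median of 28.75 peaks within 50 kb (10 genes) and Hoxa genes 22.5 (11 genes), both at percentile 100. Hoxc genes had 16 (9 genes; percentile 86.2) and Hoxd genes 16.5 (9 genes; percentile 88.6). The Hoxc median was below that of Hoxb by -12.75 peaks (percentile 0.405 of reassignments) and the Hoxd median below that of Hoxa by -6 peaks (percentile 0.575). The Hoxd call ended at 10 kb and with peaks near gene ends left out (differences of 0) and with peaks of at least 500 bp (-3 peaks, percentile 4.69). With peaks of at least 900 bp, a limit set after the data were seen, the Hoxd median (6.5) exceeded that of Hoxa (4.5), within reassignment (percentile 93.1), and the Hoxc median differed from Hoxb by -0.75 peaks (percentile 37.8). At this limit Hoxc and Hoxd lay above random lists (percentiles 100 and 99.9), as they did without matching (98.7 and 99.2). A peak at an end was found for all 10 Hoxb genes, for 10 of 11 Hoxa genes, and for 7 of 9 genes in each of the Hoxc and Hoxd clusters (percentiles 98.3, 92.7, 64.9 and 64.6). In the Hoxc and Hoxd clusters, Hoxc4, Hoxc9, Hoxd10 and Hoxd12 had none, with 15.5, 18, 17 and 16.5 within 50 kb. The call on the Hoxb share ended within 500 bp (93.5), within 2 kb (97.05) and at the gene end itself (52.4). It also ended without matching (97.2), against protein-coding genes (91.2) and with peaks of at least 900 bp (91.3). The Hoxa share was above within 2 kb (97.9) and matched on length (99.3). Hoxb5 and Hoxb4 had 31.5 and 31 peaks within 50 kb, Hoxa13 and Hoxa11 had 24.5 and 24, Hoxc10 and Hoxc11 had 19.5 and 18.5, and Hoxd8 and Hoxd9 had 19.5 and 18.5. Genes of a cluster share most of their windows, so each cluster is closer to 1 observation than to its number of genes. Hoxa, unlike Hoxb, was no longer above random lists when peaks near gene ends were left out (percentile 68.8) or with peaks of at least 900 bp (82.7).

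Positions set from general knowledge for enhancers of blood transcription factors, not checked against a source, had a peak within 1.5 kb at 10 of 12 sites, against a mean of 3.95 for the same distances applied to random named genes (middle 95% from 1 to 7; percentile 99.96). Peaks covered the positions at 9.5 and -77 kb of Gata2 (88202794 to 88203720 and 88116438 to 88117377 on chromosome 6), at 37 kb of Cebpa (35156206 to 35157125 on chromosome 7), at 12 kb of Fli1, at 1 kb of Hhex and at 16 kb of Gfi1b. Peaks also covered the positions at 19 and -4 kb of Tal1. Another ended 5 bp short of its position at 40 kb, which lies beyond the end of Pdzk1ip1. For Runx1 the nearest peak to the position at 23 kb was 858 bp away (92801340 to 92802216 on chromosome 16). The nearest peak was 1638 bp from the position at -14 kb of Spi1 and 5339 bp from that at 85 kb of Erg, outside the tolerance. Since distances were counted from the outer gene end, such a miss may also reflect a misplaced position. Mirrored positions on the other side of the same gene ends had a peak in 8 of 12 cases at this tolerance and in 3 of 12 within 0.5 kb, where 9 of the enhancer positions did. Random genes were not matched on gene density, and each distance went to a separate gene, whereas Tal1 and Gata2 gave several positions. At 1.5 kb the mirrored count also exceeded the random range, so percentile 99.96 cannot tell enhancer positions from peak-dense surroundings. Within 0.5 kb the mirrored count lay inside the random range (0 to 5) and the enhancer count above it. 

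Chromosome X carried fewer peaks than any autosome. The 19 autosomes had 59.1 ± 9.04 peaks per Mb (mean ± SD over chromosomes, range 47.6 to 81.7), and X had 21.0. Peaks per protein-coding gene were 8.25 ± 1.16 on autosomes and 4.55 on X. The share of protein-coding genes with a peak at an end was 83.1 ± 2.55% on autosomes (lowest 79.4%) and 62.9% on X. Chromosome Y had 38 peaks. Both counts of coding genes leave out olfactory and vomeronasal receptors.

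**Figure D3:**
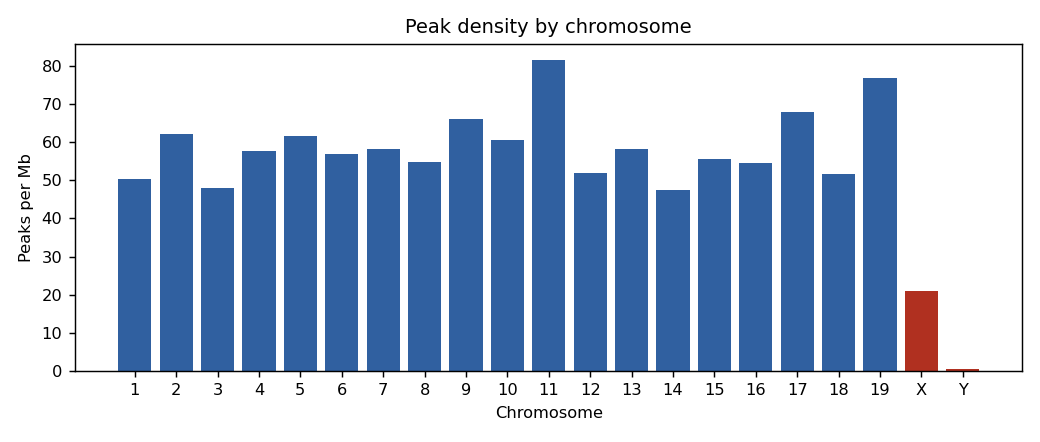
Peaks per Mb (vertical axis, from 0) for each chromosome, measured between its first and last peak, with autosomes in blue and the sex chromosomes in red. Autosomes range from 47.6 on chromosome 14 to 81.7 on chromosome 11, X has 21.0 and Y 0.419.

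The named genes with the most peaks within 50 kb lay in a few dense regions. Cxxc5, a zinc finger regulator on chromosome 18, had 32. Efna1 and Krtcap2, neighbours on chromosome 3, had 31.5 and 31. The histone genes Hist1h4f (31.5), Hist1h2bh, Hist1h3f and Hist1h3g (31 each) lay together on chromosome 13, and Dohh on chromosome 10 had 30.5. Hoxb5 and Hoxb4 completed the 10 highest. The widest peak, 1810 bp, lay on chromosome 17 at 39844625 to 39846435, 1677 bp from AY036118. The next were 1259 bp wide near Adipoq (3777 bp away), 1208 bp over an end of Gt(ROSA)26Sor on chromosome 6 (113076306 to 113077514), 1201 bp near Arhgap26 (40922 bp away) and 1190 bp over an end of Polr2a. Gt(ROSA)26Sor is the locus that carries the tdTomato reporter in these mice.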

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

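The tests on the barcode list were chosen after its size was seen. No outlier test was possible, since no value was given per library, and no contrast between groups exists in this design.

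Outside the chromosomes used in the comparisons, 53 peaks lay on 5 unplaced sequences, 26 of them on 1 sequence and 18 on another, where no gene position was used. They were noted because they are a signal outside the main measurement.

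The barcode list held exactly 20000 barcodes. The labels repeat a target of 4000 nuclei for each of the 4 libraries and do not say whether it holds for each. If it does, the target was 16000 and 20000 to 28000 nuclei were loaded. If the list came from 1 well, 5000 to 7000 nuclei were loaded, fewer than its barcodes. In either case the barcodes exceeded the target, 16000 or 4000. Which case holds is not known, so neither an excess over the nuclei loaded nor its absence is claimed. Only the round number was examined. Several wells joined end to end would leave more than 1 suffix, repeated sequences or more than 1 alphabetical run, and the list had 1 suffix, 0 repeated sequences and 1 run, which argues against that simple form of joining. A cell caller that stopped at a set number may account for the round total of 20000, and this stays open because reads per barcode were not analysed here. No biological explanation was tested. The peak set does not depend on the barcode list in a way that could be checked here.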

How the results depend on the processing

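The alternatives with peaks of at least 900 bp, matching on gene length, protein-coding genes without chemosensory receptors as background, a gene's own ends counted, the wider filter on clone names and the second draw were chosen after the data were seen, as were the pairs of lists and the settings applied to them; the others were set before the data were examined. Values below are percentiles among random lists that crossed a limit. The cause was not tested for any of them. Peak width is not known to measure peak strength, and depth limits cannot be given because no read counts were used.

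Shares of genes with a peak at an end. With the gene end itself: HSC identity 88.2, erythroid 85.4, myeloid 94.2, neural 65.0 and Hoxb 52.4 were no longer above, and ageing 98.8 was. Within 500 bp, erythroid 97.0, myeloid 95.3, neural 71.5 and Hoxb 93.5 were not above. Within 2 kb, erythroid 96.3, interferon 96.9, neural 95.1 and Hoxb 97.1 were not, and ageing 98.6 and Hoxa 97.9 were. With an overlap of 100 bp, myeloid was 97.3 and ageing 98.04. Peaks of at least 900 bp turned HSC identity 8.28, erythroid 41.8 and cell cycle 35.6 to the lower side of the random lists, and ended the calls of myeloid 73.6, interferon 75.2, immediate early 88.7, housekeeping 57.5, neural 70.5, Hoxb 91.3, liver 22.5 and skin 21.0, with ageing at 99.6. The coding background ended the calls of erythroid 90.5, myeloid 95.4, interferon 94.8, immediate early 96.9, cell cycle 91.4, housekeeping 87.8, neural 92.5 and Hoxb 91.2. Without matching, Hoxb was 97.2 and ageing 98.2. Matched on length, platelet was 97.6 and Hoxa 99.3. Ageing, 97.3 as planned, was also above in the second draw (97.7), with peaks of at least 500 bp (97.8), with all genes as background (99.7) and with the wider filter (97.535), so its call is not settled.

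Median peaks within 50 kb. Peaks of at least 900 bp ended the calls of ageing 88.5, platelet 51.7, lymphoid 97.0, housekeeping 82.8 and Hoxa 82.7, and put Hoxc 100 and Hoxd 99.9 above. Ageing and lymphoid lost their calls at 100 kb (89.1 and 95.8, with T and NK 98.8 above), with peaks over 1 kb from gene ends (92.4 and 95.9, with Hoxa 68.8), without matching (86.3 and 93.9, with Hoxc 98.7 and Hoxd 99.2 above) and matched on length (94.1 and 96.3, with cell cycle 96.7, liver 2.28 and Hoxd 99.0). The coding background gave ageing 95.8, cell cycle 94.0, housekeeping 97.4 and liver 2.36. With a gene's own ends counted, as in the first run, ageing was 97.3. At 10 kb, housekeeping 87.4 and skin 7.31 lost their calls, and endothelial 99.9, liver 1.35 and Hoxd 98.005 were called.

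Differences between pairs of lists. For shares against HSC identity in points, lymphoid was -12.7 within 500 bp, -9.09 within 2 kb and -14.2 at the gene end itself, mature B -6.25 within 2 kb and -23.3 at the end itself, and T and NK -17.3 within 500 bp and -23.3 at the end itself, none of them below reassignment. Peaks of at least 900 bp turned lymphoid (15.2), mature B (8.33), T and NK (10.6) and liver (2.08), all within reassignment, and put ageing above by 35.3. For medians in peaks, the Hoxd minus Hoxa difference was 0 at 10 kb and with peaks over 1 kb from gene ends, -3 with peaks of at least 500 bp and turned to 2 at 900 bp, where Hoxc minus Hoxb was -0.75. Against HSC identity, mature B was below with peaks over 1 kb from gene ends (-2.25), T and NK at 10 kb (-1.5) and ageing at 100 kb (-6.25).

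Of the other placements, 240 for shares and 210 for medians kept their call. The share of peaks near a gene end was 13.0% within 500 bp, 21.1% within 2 kb, 13.8% for named genes and 15.5% for peaks of at least 900 bp, of which there were 40801. Named genes with a peak were 71.1% within 500 bp, 79.1% within 2 kb, 62.0% at the end itself, 74.4% with 100 bp of overlap, 28.3% for peaks of at least 900 bp and 69.4% over all genes. Enhancer positions with a peak were 9 within 0.5 kb and 11 within 3 kb. Of 94 named genes, 17 lost their peak at the end itself and 3 within 500 bp, and 9 gained 1 within 2 kb. Motif searches, GC matching and counts per barcode suffix were not run. No paired analysis was possible because the files hold no value per library.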

Other observations

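The tests of gene density and gene families on chromosome X were set before their results were seen but after the peak counts per chromosome. The test of read depth on X, the tests on gene lists, the families and the stretches without peaks were chosen after data were seen.

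Gene families differed in how many members had a peak at an end. Of 76 ribosomal protein genes, 72 had a peak at an end (94.7%, 95% interval 87.1 to 98.5), as did 39 of 40 proteasome genes, 18 of 18 Cdk genes and 61 of 66 clustered histone genes, which had a median of 21 peaks within 50 kb. Interleukin receptor genes had a peak at an end in 37 of 41 cases (90.2%, 95% interval 76.9 to 97.3), interleukin genes in 21 of 30 (70%, 50.6 to 85.3) and Toll-like receptor genes in 12 of 12. Zinc finger genes of the Zfp series had a peak at an end in 339 of 395 cases (85.8%), with a median of 7.5 peaks within 50 kb, at percentile 0 of 1000 random lists for that number and percentile 100 for the share. Vomeronasal receptor genes (3 of 207 Vmn1r and 3 of 122 Vmn2r), keratin-associated genes (2 of 56) and cytochrome Cyp genes (39 of 101) had few.

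Antigen receptor loci, which are rearranged and used in lymphocytes, differed from each other. A peak within 1 kb of an end was found for 88 of 183 Ighv segments (48.1%, 95% interval 40.7 to 55.6) and 45 of 128 Trav segments (35.2%, 26.9 to 44.1), against 2 of 160 Igkv segments (1.25%, 0.152 to 4.44). For Trbv it was 20 of 35 (57.1%, 39.4 to 73.7). Neighbouring segments share peaks and near-identical sequence, so these intervals are too narrow, and no explanation was tested.

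Peaks around HSC, platelet and myeloid genes were more numerous than in random lists. With random lists matched on length instead of gene density, the lowest percentile of the 3 lists was 99.7. This argues against length alone as the cause for these 3 lists, which were picked after data were seen. Length and density were not matched together, and random lists did not reproduce neighbouring members that share windows. Matched on length, the ageing (94.1), lymphoid progenitor (96.3) and cell cycle (96.7) lists were no longer above. Among 5 lists of other tissues (endothelial, stroma, neural, liver and skin) the highest percentile was 92.5. At 10 kb the endothelial list reached 99.9. No excess was thus called at 50 kb around well-studied genes of these tissues. Immediate early and interferon (100 each), housekeeping (99.4) and cell cycle genes (98.005) lay above, so a general excess around well-studied genes stays open. Use of these regulatory regions in HSCs or their progeny is a hypothesis that may account for the excess, and it is untested here because no other cell type was measured in these files. Immediate early and interferon genes showed larger medians, so the excess was not limited to lineage genes.

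Chromosome X had fewer peaks than the autosomes. Low gene density is argued against as the whole cause: in 165 windows of 1 Mb matched to 2377 autosomal windows on the number of coding genes, the ratio of mean peak numbers was 0.452 (95% bootstrap interval 0.397 to 0.506, 1000 resamples of windows). Multi-copy families are argued against as the whole cause, since outside families 74.4% of 547 X genes had a peak at an end (95% interval 70.5 to 78.0), against 82.8 to 90.8% on the 19 autosomes. Peaks far from gene ends fell short by more (ratio 0.428, 0.367 to 0.486) than those near them (0.604, 0.525 to 0.683). Lower read depth from the single X of males needs this order if far peaks are weaker, but peak strength was not measured. Windows were matched on coding genes, which may itself bring the ratio near gene ends closer to that of the autosomes. The order therefore cannot tell depth from other causes, and depth stays open as a contribution. Differences in the regulation of X-linked genes and in the mapping of repeats were not tested and stay open.

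The longest stretches without a peak on autosomes were 4.15 Mb on chromosome 14 (107519960 to 111674404), which held 2 genes, both of the Slitrk family, and 4.01 Mb on chromosome 7 (19957112 to 23967803), where 63 of 102 genes inside were vomeronasal receptors.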
